A study of Rattus norvegicus with 20 samples.

How the data were processed

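RNA from retroperitoneal tissue of 20 male ZDF rats, 5 in each of 4 groups, was hybridised to Affymetrix rat whole-transcript arrays from 100 ng of total RNA per sample, per the labels' protocols. The labels call the arrays of a group biological replicates and number them within the group. The table of the whole series holds log2 values as deposited, with 1 column per array, and RMA, a method that corrects background, normalises quantiles and summarises probes, is named per the submitters' processing notes; its version and settings are not given in the sources used here. The log2 scale was read from the range of the values and from the name of the method, and was not checked against scanner files. All columns were matched to samples by their labels, and 0 columns were left unused.

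The table held 36685 features. The platform's gene table named 15653 of them, 14824 with 1 symbol and 829 with several, and 21032 were not listed there and stay unnamed here. Genes with exactly 1 symbol were kept, and of the 234 genes with several features the one with the highest mean over the 20 arrays was used, which left 14557 genes; no gene had features that passed in opposite directions. Coordinates are not given, because no genome of the array's build was used here.

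Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on group means of all 20 arrays, with 16 residual and 5.41 prior degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison as the threshold. All tests are two-sided. A count "adjusted over the list alone" applies the same adjustment to the members of a list. Gene lists, 36 in number, covered lipid, mitochondrial and glucose metabolism, immune and stress responses, and markers of other cell types; of 740 entries 551 were matched, 18 of them through an older symbol. The 35 lists with at least 5 measured members were tested with camera in limma at its preset correlation of 0.01, adjusted over lists, and again with a correlation estimated per list. Where a compared group's mean lay under the median gene level of 3.02, no fold is given for the genes named, a choice made after the values were seen, since no level was tested against background. A list score is the mean deviation of its members from their means over all arrays.

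The groups, comparisons, tests, gene lists, named-gene rule and the alternatives listed next were fixed before the data were examined. The rule took, per comparison, the 8 largest positive and 8 largest negative log2 differences among genes past the threshold whose 5 arrays all lay on 1 side of the other group's mean, leaving out symbols that start with LOC, RGD, MGC, Olr, Vom or Mir. Where fewer than 5 genes passed, it took the 5 with the smallest p of the same kind, as values. It added up to 4 members of each list past the threshold, or 2 by p where a list passed with none, and 8 fixed genes, of which 7 were measured. Olfactory receptors whose current symbols start with Or are not excluded by its wording. Which of these genes the text names was decided for length after their values were seen, and a gene named outside the rule is said to be so.

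The alternatives fixed in this way were quantile normalisation again, centring each array, leaving out dim genes, all features, the mean of a gene's features, a 1.5-fold minimum, trend and robust eBayes, array weights, the compared groups alone, the replicate number as a block, an estimated correlation, and each array left out in turn. Chosen after the data were seen were leaving out resveratrol array 1 and obese array 2, the same with rosiglitazone array 2, an exact permutation of list scores, simulated references for the gene count and signs of obese minus lean control, and marker lists for urothelium, milk protein, simple epithelium, liver and adipocytes. The left-out arrays were chosen after exploratory counts without them, and the permutation after the other list counts.

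The gene test was run on simulated data with the real means and spreads and with independent genes. For rosiglitazone minus obese over 14557 genes, 200 of them changed, limma recovered 17.9% of changes of 0.5 on the log2 scale, 80.6% of changes of 1 and 97.0% of changes of 2; it called 140 genes, of which 10 were unchanged. In 50 simulated sets with no group difference and the real correlation between genes, camera passed a median of 9 of 35 lists for rosiglitazone minus obese at the preset and 0 with an estimated correlation, so a list count at the preset is read beside both.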

Results

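Transcript levels were measured in retroperitoneal tissue of male Zucker diabetic fatty (ZDF) rats, a strain in which obese animals develop diabetes. The labels name the tissue only as retroperitoneal; Adipoq, the adipocyte hormone adiponectin, lay at 11.02 ± 0.06 on the log2 scale (SD, n = 5) in the lean control group. The series held 20 whole-transcript arrays in 4 groups of 5: lean control rats on standard chow, obese rats given a stock diet for 6 weeks, a rosiglitazone group and a resveratrol group. Rosiglitazone is an agonist of the nuclear receptor PPARG, and resveratrol is a plant polyphenol. The drug doses and the diet of the treated groups are not given in the sources used here. The labels do not say whether the treated rats were obese, and the comparisons of these groups with obese arrays take it that they were. Array medians lay between 2.46 and 2.63, and correlations between arrays between 0.895 and 0.987. The number of arrays limits the precision: the median SE of a log2 difference was 0.17 over 14557 genes.

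Obese and lean control rats were compared to find transcripts that differed between these groups in this tissue. The diets named for the groups were a stock diet and standard chow, so obesity and diet cannot be told apart here. Enzymes of mitochondrial and amino acid metabolism were among the genes that fell. Acy1, which releases amino acids from N-acetylated forms, fell by 1.26 on the log2 scale (SE 0.18), from 3.80 ± 0.35 to 2.54 ± 0.32 (SD). Ivd, the isovaleryl-CoA dehydrogenase of leucine breakdown, fell by 1.11 (SE 0.16), or 2.16-fold. Both had a limma adjusted p = 0.00556 and were below the lean control mean in 5 of 5 obese arrays. Adhfe1 fell by 1.48 (SE 0.30, adjusted p = 0.04996) and Slc25a35, a mitochondrial carrier, by 1.26 (SE 0.26, adjusted p = 0.04996). Nid2, a basement membrane protein, fell by 1.31 (SE 0.25, adjusted p = 0.0421). Each was below the lean control mean in 5 of 5 obese arrays. For Slc25a35 and Nid2 every obese array lay below every lean control array, but for Adhfe1 the groups overlapped. Adhfe1 stood at 4.002 and 4.054 on lean control arrays 1 and 3, and at 5.242 to 5.674 on lean control arrays 2, 4 and 5. Obese arrays had Adhfe1 at 2.853 to 4.157. Oaz2, an inhibitor of polyamine synthesis, rose by 1.30 (SE 0.25, adjusted p = 0.0421) in 5 of 5 arrays, and by 0.41 (adjusted p = 0.229) with the mean of its 3 features. Of these genes, only Acy1 and Ivd passed whichever single array was left out. Without obese array 2 the adjusted p was 0.147 for Adhfe1, 0.147 for Slc25a35, 0.127 for Nid2 and 0.135 for Oaz2; over all alternatives it ranged from 0.0222 to 0.147, 0.0266 to 0.147, 0.0264 to 0.127 and 0.0216 to 0.229.

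In limma, 26 of 14557 genes passed the threshold in obese against lean control arrays, 6 higher and 20 lower. Of the 6 higher genes, 4 were olfactory receptors, among them Or5ac23b and Or4f61b, at mean levels of 3.46 and 4.12 in the obese arrays; without obese array 2 both had an adjusted p = 0.127. The count was 2 without lean control array 2, lean control array 4, obese array 2 or obese array 5, 4 without obese array 3, 6 without obese array 4, and 65 without lean control array 3. It was 0 with the 2 groups fitted alone, where Acy1 and Ivd had an adjusted p = 0.0775. Lep, the hormone leptin, differed by 0.80 (SE 0.67, adjusted p = 0.638), and Adipoq by -0.08 (SE 0.17, adjusted p = 0.884). The lean control arrays were not alike in Lep. It stood at 10.2 and 10.3 on lean control arrays 1 and 3, and at 7.9 to 8.8 on lean control arrays 2, 4 and 5. Obese arrays had it at 9.3 to 10.2.

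Among the fixed lists in obese against lean control arrays, branched-chain amino acid catabolism had 18 measured members, of which 1 (Ivd) fell, 17 did not pass and all 18 had a negative difference; adjusted over the list alone, 11 fell. Its median difference was -0.53 (camera adjusted p = 2.27e-09; adjusted p = 0.357 with an estimated correlation). No member of insulin signalling and glucose uptake passed over all genes, and 8 of 17 fell when adjusted over the list alone (median -0.53, adjusted p = 0.000568; adjusted p = 0.256 with an estimated correlation). In that list the insulin receptor Insr differed by -0.67 (SE 0.17, adjusted p = 0.106) and the glucose transporter Slc2a4 by -0.68 (SE 0.25, adjusted p = 0.242). The macrophage list was the single list on the higher side (median 0.44, adjusted p = 0.00111; adjusted p = 0.774 with an estimated correlation), with 0 of 17 members past the threshold and 4 higher when adjusted over the list alone. Its members Gpnmb and Trem2 differed by 2.04 (SE 0.68, adjusted p = 0.20) and 1.08 (SE 0.32, adjusted p = 0.154); without lean control array 1, Trem2 differed by 1.38 (adjusted p = 0.0498). On obese array 2 the macrophage score was -0.89, against 0.18 to 0.61 on the other 4 obese arrays. All 8 measured urothelial markers on it were at least 2 log2 units above those arrays. Lean control arrays 1 and 3 had macrophage scores of 0.705 and 0.0336, and lean control arrays 2, 4 and 5 had -1.22 to -0.79. In all, 9 of 35 lists passed with the preset correlation and 0 with an estimated one, while simulated arrays with no difference between obese and lean control groups gave a median of 9.5 lists with the preset.

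Rosiglitazone-treated and obese arrays differed in many genes of mitochondrial and lipid metabolism. Cpt1b, the muscle-type carnitine palmitoyltransferase that admits fatty acids to mitochondria, was 8.81-fold higher (log2 difference 3.14, SE 0.43, limma adjusted p = 9.48e-05), and Fabp3, a fatty acid binding protein, was 12.5-fold higher (3.64, SE 0.43, adjusted p = 2.63e-05). Ucp1 (feature 17732790), the uncoupling protein of brown fat, was higher by 4.67 on the log2 scale (SE 0.75, adjusted p = 0.000404). Obese arrays had it at 1.22 to 2.25, under the median gene level of 3.02 and not shown to be above background, so no fold is given. Its level on rosiglitazone array 2 was 10.52, against 4.73 to 5.83 on the other 4, and the log2 difference was 3.59 (adjusted p = 9.39e-06) without that array. Alb (feature 17693539), the plasma protein albumin, rose from 4.0 ± 0.72 to 9.63 ± 0.46 (SD), a 49.7-fold difference (adjusted p = 3.30e-05). C1qtnf9, a secreted relative of adiponectin, was lower by 3.18 (SE 0.33, adjusted p = 7.64e-06), at 2.41 in rosiglitazone arrays; with the mean of its features the difference was -1.88 (adjusted p = 4.53e-05). Each of these 5 genes lay on the same side of the obese mean in 5 of 5 rosiglitazone arrays.

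**Figure D1:**
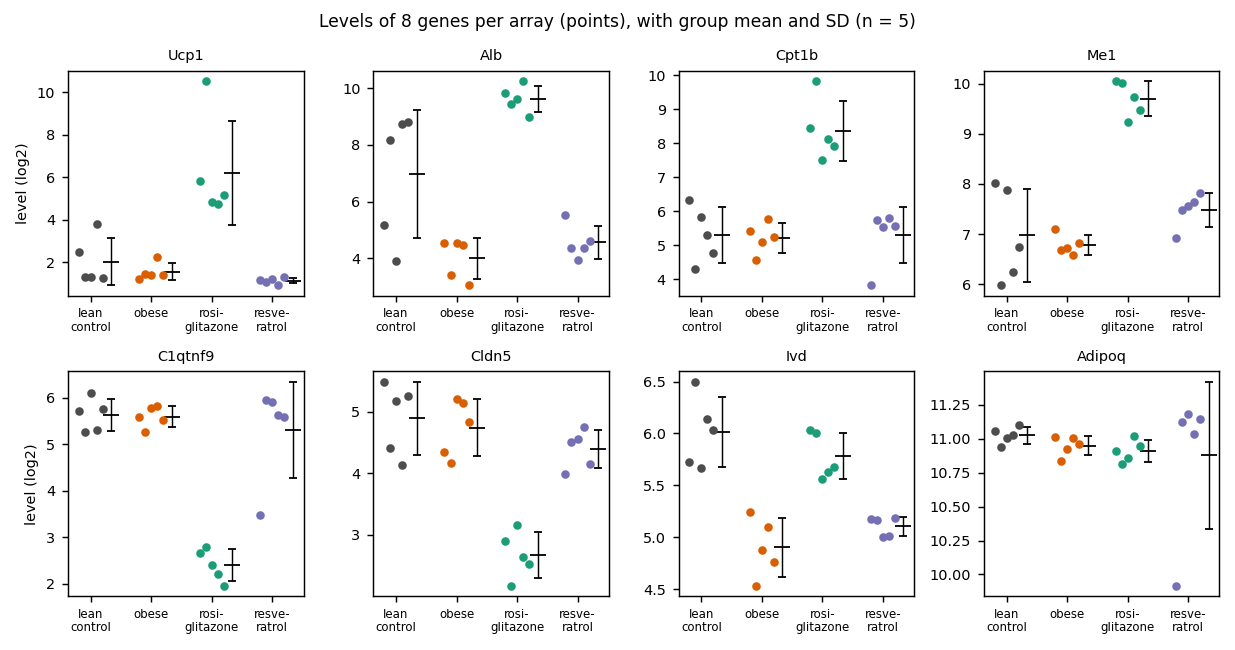
Levels (log2) of 8 genes on each of the 20 arrays, 1 panel per gene with its own vertical range; points are arrays, and the bar beside each group is its mean and SD (n = 5). Alb lay at 9.0 or above on every rosiglitazone array and at 4.54 or below on every obese array, and Adipoq was 9.92 on resveratrol array 1.

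In limma, 1436 of 14557 genes passed in rosiglitazone against obese arrays, 1047 higher and 389 lower, and 1108 of them differed by at least 1.5-fold. Oxidative phosphorylation, the respiratory chain and ATP synthase, had 53 measured members, of which 46 rose, 1 fell and 6 did not pass; adjusted over the list alone, 50 rose and 1 fell. The median difference was 1.08, with Uqcrc1 of complex III at 1.88 (SE 0.24, adjusted p = 4.44e-05) and Ndufa9 of complex I at 1.5 (SE 0.20, adjusted p = 9.48e-05). The member that fell was Atp5f1c, a subunit of ATP synthase, which fell by 0.98 and is named after its value was seen. Of mitochondrial fatty acid oxidation, 18 of 19 members rose over all genes, and adjusted over the list alone 18 rose and 1 fell (median 1.61), with Acads at 2.09 (SE 0.20) and Acadl at 1.90 (SE 0.22). Of the tricarboxylic acid cycle, 17 of 18 rose by either adjustment, over all genes or adjusted over the list alone, among them citrate synthase Cs at 1.64 (SE 0.24) and Idh3b at 1.79 (SE 0.22). Of branched-chain amino acid catabolism, 15 of 18 rose, and 16 adjusted over the list alone, with Acat1 at 1.76 (SE 0.21) and Bckdha at 1.35 (SE 0.19). The camera adjusted p of these 4 lists was 2.70e-37, 9.00e-23, 1.48e-20 and 1.60e-13. In the same order, the adjusted p was 0.0882, 0.0749, 0.0882 and 0.110 with an estimated correlation. By exact permutation of list scores, chosen after the other list counts were seen, each of the 4 had an adjusted p = 0.0278. The oxidative phosphorylation score was 1.48 on rosiglitazone array 2 and 0.42 to 0.69 on the other 4.

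De novo lipogenesis, the making of fatty acids from citrate, had 16 measured members, of which 10 rose and 6 did not pass, and 12 rose adjusted over the list alone (median 1.39). Malic enzyme Me1, which supplies NADPH, was 7.53-fold higher (2.91, SE 0.31, limma adjusted p = 7.64e-06), ATP citrate lyase Acly 5.17-fold (2.37, SE 0.32, adjusted p = 9.14e-05) and the citrate carrier Slc25a1 2.70-fold (1.43, SE 0.16, adjusted p = 1.86e-05), each higher in 5 of 5 arrays. This list passed with the preset correlation (adjusted p = 3.16e-11) and with an estimated one (adjusted p = 0.0212), but the latter was 0.0709 without resveratrol array 1 and obese array 2. Pyruvate carboxylase Pc, of the glyceroneogenesis list, was 4.26-fold higher (2.09, SE 0.22). Of the PPARG target list, 5 of 23 members rose and 18 did not pass, and 6 rose adjusted over the list alone (adjusted p = 0.00464; adjusted p = 0.476 with an estimated correlation). They included the fatty acid transporter Slc27a1 at 2.23 (SE 0.27), Slc2a4 at 1.36 (SE 0.25) and the lipid droplet protein Cidea at 2.04 (SE 0.46). Adipoq differed by -0.04 (SE 0.17, adjusted p = 0.932), Cd36 by -0.24 (SE 0.18, adjusted p = 0.468) and Lep by -1.05 (SE 0.67, adjusted p = 0.375). Of the thermogenic list, 4 of 12 members rose by either adjustment, adjusted over the list alone included: Ucp1, Fabp3, Cpt1b and Cidea (adjusted p = 0.000327; adjusted p = 0.202 with an estimated correlation). Of the antioxidant list, 5 of 15 rose, and 6 adjusted over the list alone. They included the superoxide dismutases Sod1 at 0.96 (SE 0.13) and Sod2 at 1.58 (SE 0.23). The camera adjusted p of the list was 0.00118, and 0.0882 with an estimated correlation. By exact permutation, the lipogenesis, PPARG target, thermogenic and antioxidant lists each had an adjusted p = 0.0278.

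Of the endothelial list in rosiglitazone against obese arrays, 4 of 12 members fell and 1 rose; adjusted over the list alone, 5 fell and 1 rose (median -0.34, adjusted p = 0.00555; adjusted p = 0.390 with an estimated correlation and 0.0868 by exact permutation). The tight junction protein Cldn5 was lower by 2.06 (SE 0.26, limma adjusted p = 4.49e-05), at 2.68 in rosiglitazone arrays, and Vwf, the von Willebrand factor, rose by 0.79 (SE 0.18, adjusted p = 0.00900). Of MHC class II presentation, 3 of 9 members fell, and 5 adjusted over the list alone (adjusted p = 0.0120; adjusted p = 0.476 with an estimated correlation and 0.108 by exact permutation), with the invariant chain Cd74 at -1.27 (SE 0.28) and RT1-Da at -1.40 (SE 0.33). The MHC class II score was -0.65 on obese array 2 and 0.15 to 0.30 on the other 4 obese arrays. The chemokine Ccl2 rose by 2.12 (SE 0.53, adjusted p = 0.0129), with 4 of 5 arrays above the obese mean. Lum, a matrix proteoglycan, fell by 1.22 (SE 0.31, adjusted p = 0.0155); without obese array 5 its adjusted p was 0.0506, and the range over all alternatives was 0.00132 to 0.0506. Its list, extracellular matrix and fibrosis, did not pass (median 0.34, adjusted p = 0.0609; adjusted p = 0.769 with an estimated correlation): 2 of 25 members rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell. The growth factor Ccn2 of that list rose by 1.57 (SE 0.27, adjusted p = 0.000731), and the list score was -1.28 on rosiglitazone array 2 against 0.18 to 0.74 on the other 4. In all, 16 of 35 lists passed with the preset, 12 higher and 4 lower, and 1 with an estimated correlation. An exact permutation of the list scores, chosen after the other list counts were seen, passed 10. Camera asks whether a list's members differ more than other genes, and the permutation whether the mean score differs between the groups at all. Each list that passed the permutation had the smallest p that 252 groupings can give, 0.00794. Simulated arrays with no difference between rosiglitazone and obese groups gave a median of 9 lists and at most 18 with the preset, and a median of 0 and at most 1 with an estimated correlation.

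**Figure D2:**
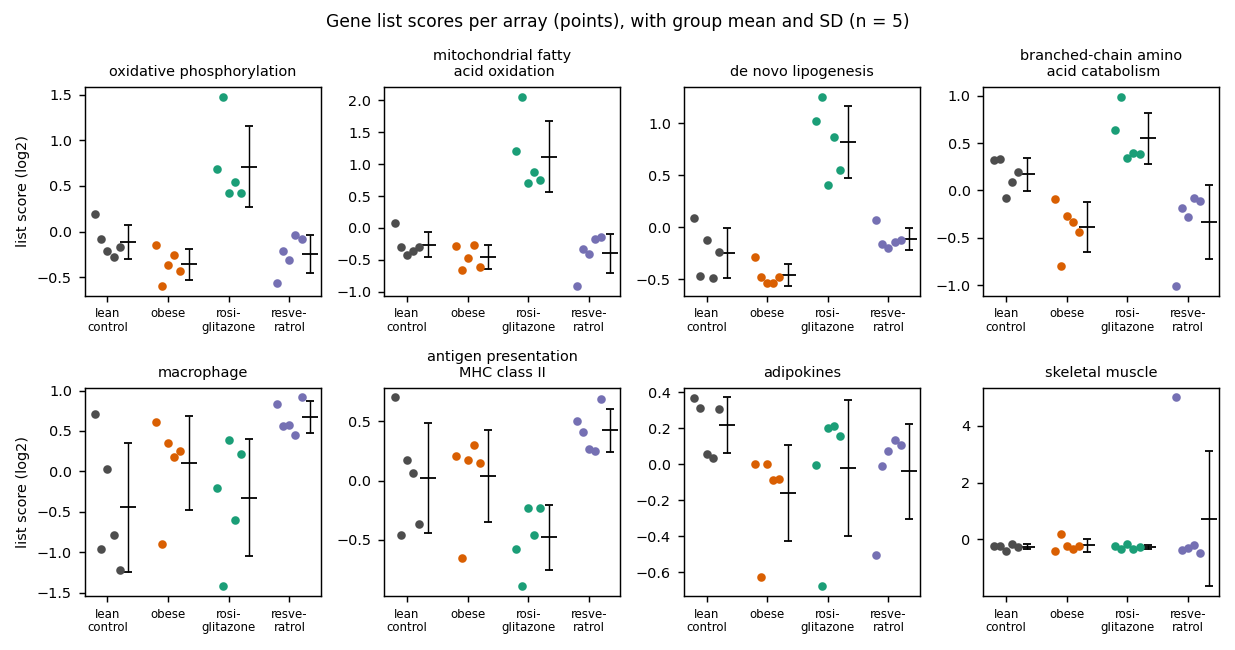
Scores of gene lists on each array (vertical axes, mean log2 deviation of the list's members from their mean over all 20 arrays); points are arrays, and bars are group means with SD (n = 5). The oxidative phosphorylation score was 0.42 or higher on every rosiglitazone array and 0.20 or lower on every other array.

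Resveratrol-treated arrays were compared with obese arrays, and no gene passed in limma. Or5ac23b, an olfactory receptor, had a difference of -1.10 (SE 0.20) and Svs1, a seminal vesicle secretory protein, of -0.72 (SE 0.13), both with an adjusted p = 0.150, the smallest of any gene, and both below the obese mean in 5 of 5 arrays. Of the metabolic genes fixed for every comparison, Slc2a4 differed by 0.05 (SE 0.25, adjusted p = 0.962), Pck1, the enzyme that starts glyceroneogenesis, by -0.45 (SE 0.41, adjusted p = 0.748) and Ucp1 by -0.41 (SE 0.75, adjusted p = 0.889). Lep differed by -0.47 (SE 0.67, adjusted p = 0.849), below the obese mean on 1 of 5 arrays, and by 0.43 (adjusted p = 0.758) without resveratrol array 1. Resveratrol array 1 had Lep at 5.89, against 10.29 to 10.50 on the other 4, a skeletal muscle score of 5.02 against -0.48 to -0.21, and the milk protein transcript Csn1s1 at 11.42, which was 5.34 on resveratrol array 2; Csn1s1 is named after its value was seen.

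The limma count of 0 genes for resveratrol against obese compares with 1286 genes at an unadjusted p under 0.05, where 727.85 would be expected by chance; with array weights 3 genes passed, among them Svs1 (adjusted p = 0.0348), and without obese array 1 the count was 1. Simulated arrays of the same size with no difference between resveratrol and obese groups also gave 0 calls. Matrix, cell cycle and macrophage lists had the smallest camera values. All 25 measured members of extracellular matrix and fibrosis had a positive difference, with a median of 0.44, but 0 passed over all genes and 0 adjusted over the list alone (adjusted p = 2.25e-06; adjusted p = 0.527 with an estimated correlation). Among them were the collagen crosslinking enzyme Loxl2 at 0.88 (SE 0.28, limma adjusted p = 0.389) and the protease Mmp2 at 0.76 (SE 0.26, adjusted p = 0.427). Without resveratrol array 1 and obese array 2 they were 0.62 (adjusted p = 0.869) and 0.40 (adjusted p = 0.876). Of the cell cycle list, 22 of 24 members had a positive difference, 0 passed and 2 rose adjusted over the list alone (adjusted p = 2.25e-06; adjusted p = 0.527 with an estimated correlation), with the mitotic kinase Plk1 at 0.62 (SE 0.17, adjusted p = 0.321). Of the macrophage list, 16 of 17 were positive, 0 passed and 1 rose adjusted over the list alone (adjusted p = 9.20e-05; adjusted p = 0.527 with an estimated correlation), with the surface marker Adgre1 at 0.86 (SE 0.24, adjusted p = 0.325), and at 0.44 (adjusted p = 0.866) without those 2 arrays. The medians of the matrix, cell cycle and macrophage lists without them were 0.24, 0.19 and 0.29, with preset adjusted p = 0.0195, 0.0119 and 0.0423, and adjusted p = 0.673 with an estimated correlation for each. De novo lipogenesis had a median of 0.26 and 0 of 16 members past the threshold, also adjusted over the list alone (adjusted p = 0.00337; adjusted p = 0.527 with an estimated correlation). The skeletal muscle list had 10 of 10 positive members and 0 past the threshold by either adjustment, adjusted over the list alone included (adjusted p = 0.00447; adjusted p = 0.601 with an estimated correlation), and an adjusted p = 0.848 without resveratrol array 1 and obese array 2. The interferon, MHC class II and fibroblast lists on the higher side and the smooth muscle list on the lower side also passed with the preset, each with an adjusted p = 0.527 with an estimated correlation. Without those arrays they had a preset adjusted p = 0.198, 0.132, 0.124 and 0.223. On obese array 2, Loxl2 was 4.33 against 5.49 to 5.91, Mmp2 6.74 against 7.76 to 8.13 and Adgre1 3.39 against 4.25 to 4.48 on the other obese arrays. In all, 9 of 35 lists passed with the preset and 0 with an estimated correlation, and simulated arrays with no difference between resveratrol and obese groups gave a median of 9.

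**Figure D3:**
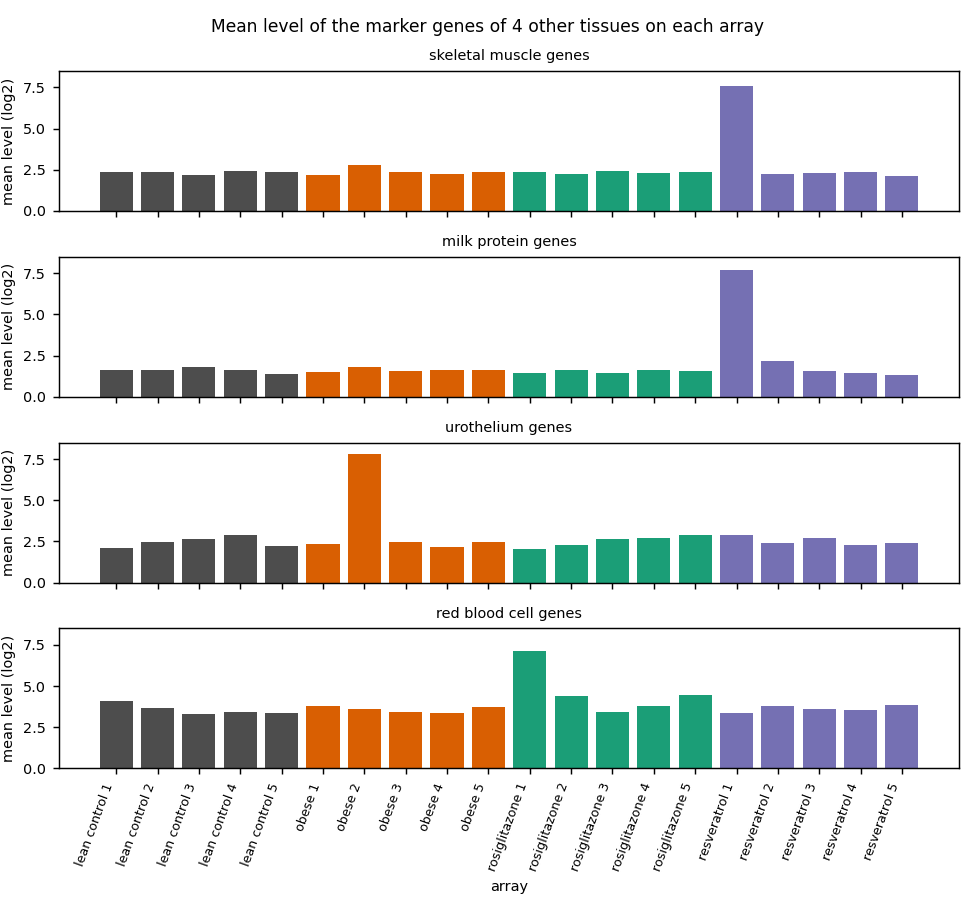
Mean levels (log2) of markers of other tissues on each of the 20 arrays, by group. The skeletal muscle score of resveratrol array 1 was 5.02, against at most 0.18 on any other array, and all 8 measured urothelial markers were at least 2 log2 units higher on obese array 2 than on the other obese arrays.

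The treatments were also compared with each other. Ucp1 was higher with rosiglitazone than with resveratrol by 5.07 on the log2 scale (SE 0.75, limma adjusted p = 0.000273), and by 4.0 (adjusted p = 3.48e-06) without rosiglitazone array 2. Resveratrol arrays had it at 0.95 to 1.31, so no fold is given. Akr1c15, an aldo-keto reductase, was 7.42-fold higher (2.89, SE 0.20, adjusted p = 2.34e-08) and Alb 33.5-fold (5.07, SE 0.69, adjusted p = 0.000154). Ccl6, a chemokine, was 4.89-fold lower (-2.29, SE 0.33, adjusted p = 0.000235), the angiotensin-converting enzyme Ace 5.66-fold lower (-2.50, SE 0.30, adjusted p = 4.63e-05) and Lum 4.31-fold lower (-2.11, SE 0.31, adjusted p = 0.000290). All 5 rosiglitazone arrays lay on the stated side of the resveratrol mean for each of these genes. Lep differed by -0.58 (SE 0.67, adjusted p = 0.716), and by -1.48 (adjusted p = 0.0390) without resveratrol array 1, over a range of adjusted p from 0.0330 to 0.920 across the alternatives. Ccl2 differed by 1.32 (SE 0.53, adjusted p = 0.152), and by 1.89 (adjusted p = 0.0107) without rosiglitazone array 2, over a range of adjusted p from 0.000730 to 0.334.

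In limma, 1004 of 14557 genes passed in rosiglitazone against resveratrol arrays, 595 higher and 409 lower. Of oxidative phosphorylation, 40 of 53 members rose, and 47 adjusted over the list alone (median 0.97, camera adjusted p = 2.63e-37; adjusted p = 0.0927 with an estimated correlation), with the succinate dehydrogenase subunit Sdha at 1.38 (SE 0.20). Of mitochondrial fatty acid oxidation, 17 of 19 rose, and adjusted over the list alone 18 rose and 1 fell (adjusted p = 2.80e-25; adjusted p = 0.0610 with an estimated correlation). De novo lipogenesis had 7 members that rose, 1 that fell and 8 that did not pass, and adjusted over the list alone 8 rose and 1 fell (adjusted p = 1.27e-07; adjusted p = 0.0610 with an estimated correlation). The member that fell was Fads1, a fatty acid desaturase, which fell by 1.48 (adjusted p = 0.0289) and is named after its value was seen. Its adjusted p was 0.0673 without rosiglitazone array 3, 0.0525 without rosiglitazone array 5 and 0.0528 without resveratrol array 2, over a range from 0.0125 to 0.114 across the alternatives. Fads1 stood at 9.19 on resveratrol array 1 and at 6.08 to 6.87 on the other 4, and it fell by 0.90 without that array. Of the macrophage list, 3 of 17 fell, and 11 adjusted over the list alone (median -0.90, adjusted p = 1.52e-08; adjusted p = 0.235 with an estimated correlation), with Adgre1 2.66-fold lower (-1.41, SE 0.24). Of MHC class II presentation, 4 of 9 fell, and 6 adjusted over the list alone (adjusted p = 4.07e-07; adjusted p = 0.132 with an estimated correlation), with RT1-Bb at -1.74 (SE 0.32). Of the cell cycle list, 5 of 24 fell, and 10 adjusted over the list alone (adjusted p = 2.39e-09; adjusted p = 0.0950 with an estimated correlation), with the checkpoint kinase Bub1 at -0.76 (SE 0.18). Without resveratrol array 1, obese array 2 and rosiglitazone array 2, Bub1 was -0.60 (adjusted p = 0.0693, over a range from 0.00223 to 0.0693). The fibroblast list had 3 of 14 members lower and 1 higher, and adjusted over the list alone 4 fell and 1 rose (adjusted p = 0.0156; adjusted p = 0.444 with an estimated correlation), with the matrix proteoglycan Dcn at -1.26 (SE 0.27). Resveratrol array 1 had Adgre1 at 5.95, against 4.66 to 4.96 on the other 4 resveratrol arrays. In all, 18 of 35 lists passed with the preset, 13 by exact permutation and 0 with an estimated correlation; simulated arrays with no difference between rosiglitazone and resveratrol groups gave a median of 6 and at most 15.

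The remaining comparisons with the lean control group gave 755 genes for rosiglitazone, 383 higher and 372 lower, and 18 for resveratrol, 4 higher and 14 lower, in limma. The resveratrol count was 206 without lean control array 1, 36 without lean control array 3, and 0 without lean control array 2, lean control array 4, resveratrol array 1 or resveratrol array 4. It was 7 without lean control array 5, 3 without resveratrol array 2, and 1 without resveratrol array 3 or resveratrol array 5. Of the 26 genes that differed between obese and lean control arrays, 12 also passed in rosiglitazone against obese arrays, 10 lower and then higher and 2 higher and then lower. The 10 included Acy1 at 1.33 (adjusted p = 9.48e-05), Ivd at 0.88 (adjusted p = 0.00130) and Slc25a35 at 1.51 (adjusted p = 0.000788) for rosiglitazone minus obese, and are named for this comparison after their values were seen. Of the 26, 24 had the opposite sign in rosiglitazone minus obese, and 25 in resveratrol minus obese, where none passed. The 26 genes of smallest p in simulated sets with no difference gave a median of 26 opposite signs for either comparison. The signs therefore say nothing of a treatment. Independent lists of these sizes would share 2.56 genes. Simulated unchanged groups called a median of 0 genes and give no reference for the 12. With the obese arrays split between the comparisons the median overlap was 1 gene, and it was 2 genes without resveratrol array 1 and obese array 2. Fewer genes passed in obese minus lean control there, a median of 2 with the split and 2 without those arrays. The fall from 12 therefore does not show that a smaller share of the calls was shared.

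The comparisons with the obese group use the same obese arrays. Simulated values below are medians with their range. For obese minus lean control and rosiglitazone minus obese, the correlation of log2 differences across genes was -0.494 against a simulated -0.478 (-0.941 to 0.377). The covariance was -0.0585 against -0.0207 (-0.0848 to 0.0173). With the obese arrays split between the comparisons their medians were -0.245 (-0.341 to -0.171 over the splits) and -0.0358 (-0.0457 to -0.0239). Genes are not independent replicates. For obese minus lean control and resveratrol minus obese, they were -0.378 against -0.486 (-0.909 to 0.0855) and -0.0279 against -0.0202 (-0.0829 to 0.00299). With the split they were -0.0660 (-0.129 to 0.0646) and -0.00587 (-0.0117 to 0.00637). For rosiglitazone and resveratrol, each against obese, the correlation was 0.378 against 0.552 (-0.280 to 0.884) and the covariance 0.0404 against 0.0216 (-0.0104 to 0.0882), with 0 shared calls. With the split they were 0.128 (0.0685 to 0.211) and 0.0156 (0.0093 to 0.0265). Each observed value with shared obese arrays lay within its simulated range. Over the splits, correlation and covariance stayed negative for obese minus lean control and rosiglitazone minus obese. They stayed positive for rosiglitazone and resveratrol, each against obese. They took either sign for obese minus lean control and resveratrol minus obese. The splits reuse the same arrays, and no simulated values were set beside them.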

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

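The tests of the 3 patterns weighed here, and the marker lists other than those for skeletal muscle, mesothelial and red blood cells, were chosen after the results were seen. In each group of 5 arrays, the gap between the most distant array and its nearest neighbour was divided by the range of the group. Of 568 such ratios, 74 were above 0.71. Chance gives about 1 in 20, or 28.4, for independent ratios. The ratios are not independent, and some genes were named after their values were seen, so 28.4 is only a rough reference. The 74 came from 26 of 144 list scores and 48 of 424 gene levels. Resveratrol array 1 held 22 levels and 11 scores, and obese array 2 held 12 levels and 6 scores. Each value below is a log2 level or a list score with its ratio in parentheses.

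Levels below the rest of the group on resveratrol array 1 were Cdkn2c 3.94 (0.778), Lep 5.89 (0.954), Adipoq 9.92 (0.883), Pck1 7.43 (0.852), Cd36 9.72 (0.958), Cpt1b 3.82 (0.859) and Prg4 4.24 (0.728). Further low levels there were C1qtnf9 3.47 (0.85), Nnat 7.14 (0.939), Cidea 6.47 (0.787), Acadl 7.19 (0.738) and Nsdhl 3.60 (0.832). Levels above the rest on resveratrol array 1 were Ccl2 6.69 (0.85), Ace 7.14 (0.838), Sod1 7.49 (0.772), Adgre1 5.95 (0.763), Scd2 6.60 (0.83), Acss2 7.30 (0.765) and Ckm 8.16 (0.869). Further high levels there were Myl11 8.89 (0.934), Tnnt3 8.40 (0.86) and Fads1 9.19 (0.745). List scores below the rest on resveratrol array 1 were PPARG targets in adipocytes -1.15 (0.773), glyceroneogenesis and triglyceride synthesis -1.33 (0.805), lipolysis -0.77 (0.783), peroxisomal fatty acid oxidation -0.56 (0.718), tricarboxylic acid cycle -1.08 (0.76), thermogenic and brown adipocyte -0.84 (0.816) and branched-chain amino acid catabolism -1.01 (0.776). Further low scores there were cholesterol synthesis -0.65 (0.821) and adipokines -0.50 (0.77). List scores above the rest on resveratrol array 1 were inflammatory cytokines and chemokines 0.35 (0.717) and skeletal muscle 5.02 (0.953).

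Levels below the rest of the group on obese array 2 were Nid2 4.22 (0.76), Zfp36 5.51 (0.737), Eci2 5.67 (0.746), Cd74 9.38 (0.72), RT1-Da 7.04 (0.8), Adgre1 3.39 (0.785) and Loxl2 4.33 (0.736). Further low levels there were Mmp2 6.74 (0.732), Ccl6 7.72 (0.844) and Cd68 5.45 (0.72). Levels above the rest on obese array 2 were Or5ac23b 3.77 (0.754) and Ckm 3.33 (0.729). List scores below the rest on obese array 2 were lipolysis -0.53 (0.766), adipokines -0.63 (0.853), macrophage -0.89 (0.716), antigen presentation MHC class II -0.65 (0.841) and immediate early genes -0.44 (0.735). List scores above the rest on obese array 2 were kidney 0.48 (0.805).

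Levels below the rest of the group on rosiglitazone array 2 were Cdk1 1.23 (0.711). Levels above the rest on rosiglitazone array 2 were Ndufs7 8.14 (0.76), Ucp1 10.52 (0.809) and Tfam 5.33 (0.726). List scores below the rest on rosiglitazone array 2 were adipokines -0.68 (0.753), extracellular matrix and fibrosis -1.28 (0.722) and smooth muscle and pericyte -0.95 (0.773). List scores above the rest on rosiglitazone array 2 were oxidative phosphorylation 1.48 (0.75) and thermogenic and brown adipocyte 2.28 (0.738).

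Levels above the rest on lean control array 1 were Idh3b 8.59 (0.765), Acly 7.23 (0.771) and Uqcrc1 6.73 (0.762). List scores above the rest on lean control array 1 were mitochondrial fatty acid oxidation 0.07 (0.734) and tricarboxylic acid cycle 0.28 (0.732).

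Of the remaining arrays, values apart from their group were Igsf10 5.83 (0.729) on lean control array 5, de novo lipogenesis -0.28 (0.775) on obese array 1, Thbs4 3.62 (0.738) and Prg4 6.29 (0.713) on obese array 1. There were also Acsm1 1.80 (0.845) on obese array 3, Ucp1 2.25 (0.783) on obese array 4, red blood cell 3.25 (0.726) on rosiglitazone array 1, Acy1 4.14 (0.714) on rosiglitazone array 1 and Prg4 8.77 (0.791) on rosiglitazone array 5.

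The transcripts of other tissues on resveratrol array 1 and obese array 2 may come from pieces of other tissue in those samples, a hypothesis. On resveratrol array 1, 10 of 10 measured skeletal muscle genes (Myl11 8.89) and 7 of 8 milk protein genes (Csn1s1 11.42) stood at least 2 log2 units above the mean of the other resveratrol arrays, though resveratrol array 2 had Csn1s1 at 5.34 and Csn3 at 2.94; of these lists, 1 muscle gene and 0 milk protein genes lay above the median level in lean control tissue. An effect of resveratrol as large on the other resveratrol arrays as on array 1 is argued against by their highest muscle score, 0.096 above the mean of the obese arrays other than array 2, where array 1 was 5.33 above it; a smaller effect stays open, since their mean minus the highest obese array was -0.518, and -0.107 without obese array 2. On obese array 2, 8 of 8 urothelial markers stood as high (Upk1b 9.35), of which 2 lay above that median and 1 is in another list; mesothelial tissue as their source is argued against by 12 arrays with a higher mean of Msln, Upk3b, Lrrn4 and Gpm6a, whose highest median of the urothelial markers minus that of obese array 2 was -5.042. Some mesothelial tissue stays open, with a list median of 1.901 and a median of -0.171 over Msln (0.95), Lrrn4 (-0.54) and Gpm6a, beside Upk3b at 1.01; where any such tissue would come from stays open too, and for the milk protein and urothelial genes no biological explanation was tested.

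Alb rose in the rosiglitazone group, and liver tissue in those samples is argued against by the 14 other liver markers, whose median difference was -0.072, with 13 under 1 log2 unit; 3 of the 14 lay above the median level in lean control tissue and 1 is in another list. The most abundant of them were Rbp4, at 8.47 in rosiglitazone and 7.91 in obese arrays, and Tf, at 6.93 and 7.58. A single rosiglitazone array is argued against as well, since the lowest log2 difference with 1 of them left out was 5.48. Lean control arrays spanned 3.91 to 8.80, and rosiglitazone minus lean control was 2.67 (limma adjusted p = 0.0226). Alb stood at 5.19 and 3.91 on lean control arrays 1 and 3, and at 8.16 to 8.80 on lean control arrays 2, 4 and 5. Rosiglitazone arrays had it at 9.0 to 10.25. An effect of rosiglitazone on Alb in this tissue may be the source, as a hypothesis found and tested on the same arrays.

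Mitochondrial lists were higher in the rosiglitazone group. A larger share of adipocytes in the tissue is argued against as the whole source by 16 adipocyte markers. This holds only if rosiglitazone does not itself lower the transcripts of these markers, which was not tested. The median difference of the markers was 0.111, against 1.08 for oxidative phosphorylation. Single markers ranged from -1.05 (Lep) to 1.85 (Lgals12), and 2 passed the threshold, both higher. The SD of the marker median over resampled sets of the markers was 0.221, a spread between genes and not between rats. All 16 lay above the median level in lean control tissue, 12 are in other lists, and their high level would hide a small change of share. The difference does not rest on rosiglitazone array 2 alone, since the oxidative phosphorylation score differed by 1.07 with it and by 0.876 without it. An effect of rosiglitazone on these genes may be the source, as a hypothesis, and a change in the kind of adipocytes stays open and was not tested.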

How the results depend on the processing

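Leaving out resveratrol array 1 and obese array 2, the same with rosiglitazone array 2, and the exact permutation were chosen after the data were seen. Of 158 gene and comparison pairs, 96 passed; 17 of them lost the call without some single array. Of 1580 values with 1 array left out, 1462 kept sign and side of the threshold, 104 lost the call, 4 gained it and 10 changed sign; none of the changed signs belonged to a gene past the threshold. The cause was not tested for any change below except where fewer arrays or genes entered the test.

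For obese minus lean control, the 26 genes became 8 with quantile normalisation again, 2 with each array centred, 44 without dim genes, 4 over all features, 13 with the mean of a gene's features, 0 with the 2 groups alone, 3 with the replicate number as a block, 2 without resveratrol array 1 and obese array 2, and 17 also without rosiglitazone array 2. For resveratrol minus lean control, the 18 genes became 0 over all features, 398 with array weights, 0 with the 2 groups alone, 71 with the block and 59 without the 3 arrays. For resveratrol minus obese, array weights gave 3. With an estimated correlation, 0 lists passed for obese minus lean control and 1 for rosiglitazone minus obese. The count was 0 for resveratrol minus obese and 0 for rosiglitazone minus resveratrol. At the preset correlation, leaving out dim genes took the lists from 9 to 5 for obese minus lean control. It took them from 9 to 5 for resveratrol minus obese as well. The exact permutation passed 0 lists for obese minus lean control, 10 for rosiglitazone minus obese and 0 for resveratrol minus obese. The 252 groupings give no p below 0.00794, so a list passes only where enough other lists also reach that p. In obese minus lean control the glyceroneogenesis, branched-chain amino acid, insulin signalling, adipokine and immediate early lists reached it, with an adjusted p = 0.0556 by exact permutation. Those counts of 0 therefore do not show that no list differed. The overlap of 12 genes became 1 with the obese arrays split, 19 without dim genes, 5 with quantile normalisation, 3 with the block and 2 without resveratrol array 1 and obese array 2. In the same order, the genes past the threshold in obese minus lean control numbered 2 (a median over the splits), 44, 8, 3 and 2.

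With 1 array left out, genes ranged from 2 to 65 for obese minus lean control, 1007 to 1482 for rosiglitazone minus obese, 0 to 1 for resveratrol minus obese, 685 to 965 for rosiglitazone minus resveratrol, 511 to 931 for rosiglitazone minus lean control and 0 to 206 for resveratrol minus lean control. Lists ranged from 8 to 12, 13 to 17, 7 to 13 and 15 to 19 for the comparisons of obese with lean control, rosiglitazone with obese, resveratrol with obese and rosiglitazone with resveratrol.

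None of the values below passed the threshold in the fit of all arrays, and their signs changed. For resveratrol minus obese, array weights gave Lep 0.092 and Adipoq 0.084; without resveratrol array 1 and obese array 2, and again without rosiglitazone array 2, Lep was 0.28, Adipoq 0.15 and Cd36 0.034. With 1 array left out, Lep ranged from -0.72 to 0.43, Adipoq from -0.14 to 0.17, Cd36 from -0.23 to 0.081 and Slc2a4 from -0.041 to 0.18. For rosiglitazone minus resveratrol, array weights gave Adipoq -0.13 and Pck1 -0.25; without the 2 arrays they were -0.21 and -0.14, and without the 3 arrays -0.19 and -0.55. With 1 array left out, Adipoq ranged from -0.21 to 0.10 and Pck1 from -0.24 to 0.55. For rosiglitazone minus obese, Pck1 ranged from -0.69 to 0.10.

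Pairing of arrays by replicate number was neither shown nor excluded. The 30 correlations of residuals between arrays of the same number lay between -0.207 and 0.356, 5 of them above 0.1. Of 20 arrays, 6 were closest to one of their own number. Correlations between arrays of different numbers were not set beside these values.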

Other observations

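The tests of how often other splits of the arrays gave as many calls were written before their results were seen; the comparison of the obese minus lean control count with simulated sets and genes named outside the rule were chosen after. Of peroxisomal fatty acid oxidation in rosiglitazone against obese arrays, 6 of 14 members rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.000251; adjusted p = 0.211 with an estimated correlation and 0.0595 by exact permutation). Eci2, an isomerase of unsaturated fatty acid breakdown, was 2.55-fold higher (1.35, SE 0.23, limma adjusted p = 0.000758), and the bifunctional enzyme Ehhadh 2.82-fold (1.5, SE 0.31, adjusted p = 0.00320), each in 5 of 5 arrays. The member that fell was Scp2, a sterol carrier, which fell by 1.15 (adjusted p = 0.0433) and is named after its value was seen; its adjusted p was 0.125 without obese array 2, 0.119 without rosiglitazone array 4 and ranged from 0.00501 to 0.146 over the alternatives. Of smooth muscle and pericyte genes, 2 of 9 fell, also adjusted over the list alone (adjusted p = 0.00464; adjusted p = 0.255 with an estimated correlation and 0.181 by exact permutation), with Casq2 2.22-fold lower (-1.15, SE 0.20) and Notch3 1.64-fold lower (-0.71, SE 0.17); the list had an adjusted p = 0.345 without resveratrol array 1, obese array 2 and rosiglitazone array 2. Its score was 1.25 on obese array 2, the array with urothelial markers, against -0.33 to 0.17 on the other 4 obese arrays, and -0.95 on rosiglitazone array 2 against -0.22 to -0.01 on the other 4.

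Genes outside these lists also differed with rosiglitazone against obese. Prg4, the joint lubricant lubricin, was 8.07-fold higher (3.01, SE 0.38, limma adjusted p = 4.60e-05), and the matrix thrombospondin Thbs4 was higher by 3.35 (SE 0.45, adjusted p = 9.48e-05), and by 3.97 (adjusted p = 2.78e-08) without rosiglitazone array 2. Vat1l was higher by 2.86 (SE 0.24, adjusted p = 6.72e-07). Nnat, neuronatin, was 5.40-fold lower (-2.43, SE 0.45, adjusted p = 0.00141). Each lay on the same side of the obese mean in 5 of 5 arrays.

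Splits of the 10 arrays of a comparison into other groups of 5 tested whether arrays grouped at random give as many calls, with 100 splits each and the real one included. For obese minus lean control, 2 splits gave at least the real 26 genes, and the highest other gave 94. For rosiglitazone minus obese it was 1 split, the real one, with 1436 genes against 146 in the highest other. For rosiglitazone minus resveratrol it was 1, with 1004 genes against 59, and for rosiglitazone minus lean control 1, with 755 against 270. For resveratrol minus lean control, 2 splits gave at least 18 genes, and the highest other gave 106. The share of splits with at least the real count was under 0.05 for each of these 5 counts. For the counts with rosiglitazone only the real split reached it, which argues against chance. For obese minus lean control and resveratrol minus lean control chance is not excluded, since another split called 94 and 106 genes. With 1 array left out, the resveratrol minus lean control count ranged from 0 to 206, and no simulated sets were set beside it. Of 100 simulated sets with no group difference, 1 gave at least 26 genes for obese minus lean control, with 318, and that count was 2 without any 1 of 4 arrays and 0 with the 2 groups fitted alone. Single splits that called several times the real 26 or 18 genes point to a structure of the samples or to the correlation between genes that the simulation holds, and neither was tested. For resveratrol minus obese the real count and the highest other were 0 genes; all 100 splits then give at least as many, and the count says nothing of chance.

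Chance is not excluded for any count of lists at the preset correlation. In obese minus lean control, 20 of 100 splits gave at least the real 9 lists, with 15 in the highest other. In rosiglitazone minus obese, 9 gave at least 16, with 17 in the highest other. In resveratrol minus obese, 52 gave at least 9, with 17 in the highest other, and in rosiglitazone minus resveratrol, 20 gave at least 18, with 22 in the highest other.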
